A study of Rattus norvegicus with 12 samples.

How the data were processed

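The samples were primary cultures of ventricular cardiomyocytes from 1-day-old Wistar rats, kept for 24 h in a reduced-serum medium and then exposed for 3 h to ethanol vehicle, CVZ, COR or ALD, with or without 10 µM RU486 given beforehand. There were 12 Affymetrix arrays of 31099 probe sets in 8 groups: 4 groups of 2, with 1 array in each of 2 experiments (4 arrays in the first), and 4 groups of 1, the RU486 groups, run only in the second (8 arrays). The deposited values are intensity on a linear scale, per the labels MAS5 signals. Tested on the files, every array's value had a median of 1, and times 1 constant per array all values became multiples of 0.1, so the signals had been divided by the array's own median and the median before division could be read back. No depth exists for arrays, and their number limits the precision. The arrays with RU486 and the ALD array of the second experiment had the highest medians before division, and median division removes a constant factor but not a change of shape.

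Values were put on the log2 scale after adding a pseudocount of 0.0696, the 10th percentile of all values, left unrounded because it is below 1. After 57 control probe sets were set aside 31042 remained, and those with a mean log2 value above the 40th percentile, a geometric mean of signal plus pseudocount of 0.63, were tested (18625 probe sets, 10082 named genes). Probe sets were named from the array annotation with current rat symbols. The fit was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) with the 8 groups and the experiment as a block. The residual degrees of freedom were 3, and with 12.2 from the prior the total was 15.2, so the errors lean on the variance shared by all probe sets, and the lone RU486 arrays were taken to vary like the others. A change was called at a Benjamini-Hochberg adjusted p below 0.05, and intervals are 95%. There were 11 comparisons: each ligand and the mean of the 3 against vehicle, the ligands against each other, RU486 against vehicle, ligand plus RU486 against ligand, ligand plus RU486 against RU486, and the difference between the ligand response with and without RU486 (the interaction). In the comparisons with RU486 on top the 3 ligands were averaged. The arrays of an experiment were paired by the block: after removal of group means the deviations of the first experiment correlated between groups at 0.512 to 0.567, while replicates correlated at 0.946 to 0.950, and no values were identical between replicates.

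The groups, comparisons, threshold, filter, pseudocount rule, 26 gene lists and rule for naming genes were fixed before the data were examined. Genes were named by 1 probe set each, that with the highest mean. For each ligand these were up to 14 rises and 8 falls with the same sign in both experiments, for other comparisons up to 5 of each, in each list any member past the threshold and up to 4 others of highest signal, and the receptors Nr3c1 and Nr3c2. Not every gene that met this rule is reported. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists with at least 3 measured members, and with an estimated correlation and fry as alternatives. With an estimated correlation camera rests on the 3 residual degrees of freedom, which raises its p-values at any correlation. The lists were GR targets, mineralocorticoid targets, receptors and chaperones, fatty acid use, glucose use, amino acid catabolism, prostanoid synthesis and receptors, purine turnover, cytokines and inflammation, fetal and hypertrophic genes, immediate early genes, circadian clock, and atrophy and autophagy. The others were calcium and ion channels, extracellular matrix and fibrosis, oxidative stress, MAPK and G protein feedback, proliferation, and markers of cardiomyocytes, fibroblasts, smooth muscle, endothelium, macrophages, epicardium, erythroid and Schwann cells. Some genes stand in several lists, such as Sgk1 and Per1 (GR and mineralocorticoid), Klf15 and Ddit4 (GR and atrophy) and Glul (GR and amino acid). The lists are therefore not separate evidence. Another 3 lists, of ATF4-linked genes, chaperones of the endoplasmic reticulum and sterol synthesis, were chosen after the results had been seen. Their p-values were adjusted over these 3 lists alone and cannot be compared with those adjusted over the 24.

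The procedure was tested on simulated data with the same design. Of changes of log2 1 it recovered 54% for CVZ, 45% for RU486 alone and 68% for RU486 on top of the ligands, and of changes of log2 2 it recovered 95%, 79% and 96%, with 3.25%, 1.59% and 3.53% of calls false. The shifted list was called and 0 unshifted lists were. The simulated noise was normal, drawn from the fitted prior variance, independent between genes and alike for the lone RU486 arrays. These rates therefore cannot test those assumptions. The correlation of ligand responses was compared with 100 simulations of noise without any response, in which the ligands shared the vehicle arrays.

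Alternatives tried were no experiment block, only the 8 arrays without RU486, quantile normalization, median centring, 4 times the pseudocount and the pseudocount divided by 4, no filter and a 60th percentile filter, eBayes without a trend and with robust weights, 1 probe set per gene or the mean over a gene's probe sets, a 2-fold minimum, a 2-fold minimum in both experiments without a test, and each array left out. Scaling to a mean trimmed by 2 percent, only probe sets with a single symbol, and the genes raised by both CVZ and COR as a set for reading RU486 were chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Fibroblasts named in the culture notes have no array, and raw intensity files were not used.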

Results

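Gene expression was measured in primary cultures of rat ventricular cardiomyocytes exposed for 3 h to vehicle, cortivazol (CVZ), corticosterone (COR) or aldosterone (ALD). The same conditions were also run after pretreatment with 10 µM RU486, an antagonist of the glucocorticoid receptor (GR). Vehicle, CVZ, COR and ALD had 1 array in each of 2 experiments (n = 2), and each RU486 condition had 1 array in the second experiment (n = 1). Changes are log2 differences fitted with the experiment as a block, given with the standard error. Fitted comparisons of RU486 groups with groups without RU486 therefore also draw on arrays of the first experiment. The p-values measure only the spread between these arrays, because nothing says whether the experiments were separate culture preparations. Standard errors, intervals and p-values lean on the variance shared by all probe sets, so they can be tighter than a gene's own 2 replicates. The doses of the ligands are not in the labels, so a difference between ligands may be one of dose. Of 18625 tested probe sets, CVZ changed 1483, COR 632 and ALD 177 at adjusted p below the threshold of 0.05.

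CVZ raised Fkbp5, which encodes a co-chaperone of steroid receptors, 23.2-fold (log2 4.54 ± 0.14, adjusted p = 2.3e-11, n = 2), from a mean signal of 1.84 ± 0.46 (SD) to 43.6 ± 0.20. Klf15, a transcription factor that restrains cardiac growth and directs amino acid and lipid metabolism, rose 9.24-fold (log2 3.21 ± 0.11, adjusted p = 3.6e-11), and Tent5b, a nucleotidyltransferase, rose from 0.348 to 12.5 (adjusted p = 9.9e-11). Ptgs2, which encodes cyclooxygenase 2, rose from 0.795 ± 0.20 to 13.2 ± 0.30 (log2 3.96 ± 0.29, adjusted p = 1.3e-07). Orm1, an acute phase plasma protein, rose from 0.228 to 12.5 (adjusted p = 3.4e-08). The vehicle signals of Orm1, Tent5b, Rasgrp1, Otulinl, Per1 and Sult1a1 and the CVZ signal of Ccl7 lay below the mean level of 0.63 needed for testing, so the sizes of their changes depend on the pseudocount. Among the falls were Ccl2, encoding a chemokine that draws monocytes, at log2 −2.75 ± 0.19 (adjusted p = 8.1e-08), and its neighbour Ccl7 at −3.05 ± 0.31 (adjusted p = 5.1e-06). Sema6d, a transmembrane semaphorin, fell by log2 2.05 ± 0.15 (adjusted p = 1.4e-07). The GR itself, Nr3c1, fell by log2 0.77 ± 0.12 (adjusted p = 0.00056, from 10.6 ± 1.5 to 6.15 ± 0.16), while the mineralocorticoid receptor Nr3c2 was not called (log2 −0.09, 95% interval −0.60 to 0.42).

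**Figure D1:**
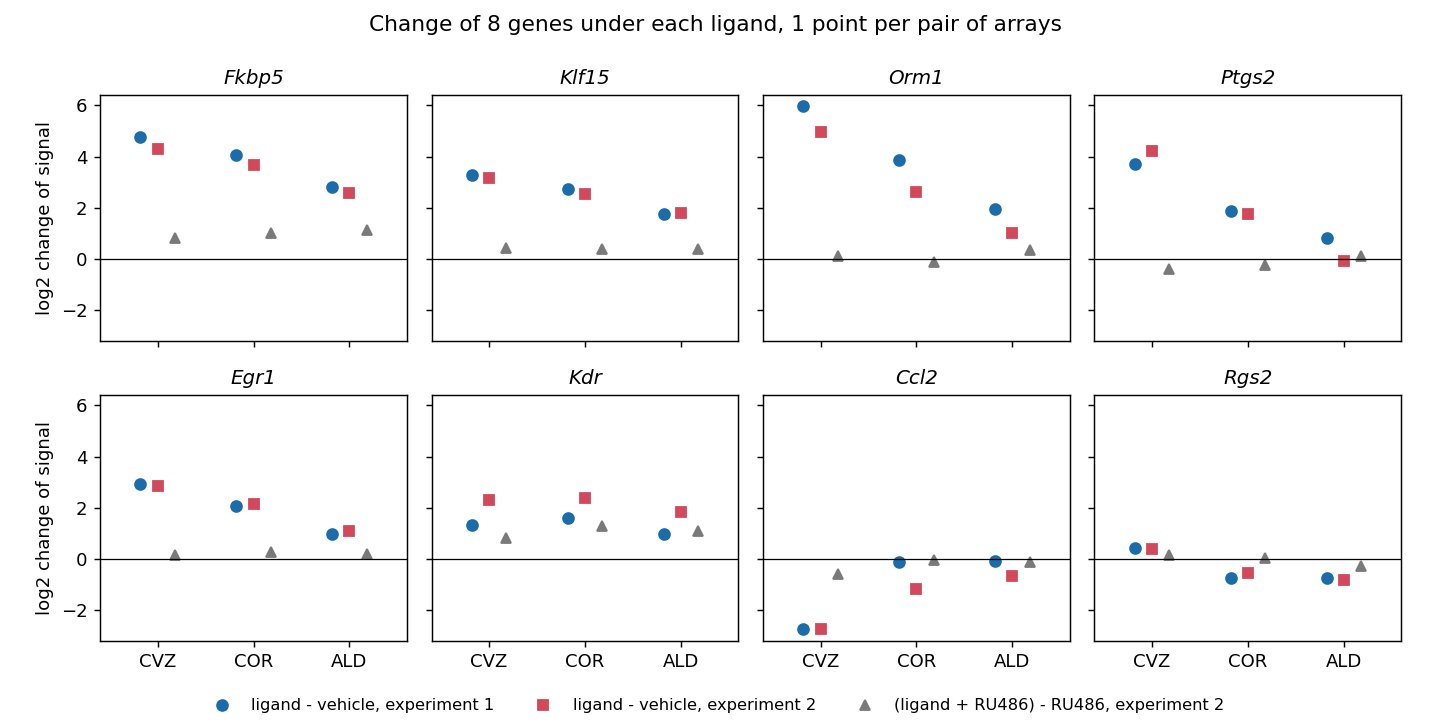
Log2 change of 8 genes under each ligand against the vehicle array of the same experiment, and under each ligand plus RU486 against RU486 alone; each point is 1 array minus 1 array. Fkbp5 under CVZ was 4.78 in the first experiment, 4.29 in the second and 0.81 with RU486.

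The CVZ response covered 889 rises and 594 falls, or 534 and 352 named genes, and 630 of the 1483 probe sets changed at least 2-fold. Under quantile normalization there were 836 rises and 774 falls, and with trimmed-mean scaling 782 and 807. Further rises were those of Spata13 (a guanine nucleotide exchange factor, log2 4.61), Sult1a1 (a phenol sulfotransferase, 3.61), F3 (tissue factor, 3.61), Cdc42ep2 (a Cdc42 effector, 3.43), Rasd1 (a Ras-like protein first found as dexamethasone induced, 3.40) and Crispld2 (a secreted protein, 3.37). Zfp189, a zinc finger protein, rose by 3.21. Ccl20, a chemokine, rose by 3.42 ± 0.20, against the direction of Ccl2. Falls included Phlda1, a pleckstrin homology protein, from a signal of 1.41 to 0.0690, which is no more than the pseudocount and leaves the size of the fall open (adjusted p = 0.00011), the growth factor Fgf18 (−2.29) and the transcription factor Sox4 (−1.91 ± 0.11). Of the 113 genes called and named here, 86 lost the call without the experiment term, 36 when 1 array was left out and 5 under another scaling of the arrays. The 27 kept under all of these and under other pseudocounts include Fkbp5, Klf15, Tent5b, Ptgs2, Orm1, Sema6d and Phlda1, and Ccl2, Ccl7 and Nr3c1 were lost only without that term. The count was 202 without the term and 646 without a mean-variance trend.

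Among 23 measured GR targets, 20 rose with CVZ and 3 were not past the threshold, with 20 up and 1 down when p was adjusted over the list alone (median log2 1.74). Within the experiments the medians were 1.73 and 1.80, and the list was past the threshold in camera (adjusted p = 1.7e-32; adjusted p = 0.067 with an estimated correlation). The 13 mineralocorticoid targets gave 9 rises and 4 not past, 9 when adjusted over the list alone, with a median of 0.72 (camera adjusted p = 1.1e-11; adjusted p = 0.078 with an estimated correlation). Examples were Sgk1, a kinase that raises sodium channel activity (log2 2.16), and Per1, a clock repressor (3.04 ± 0.27). Both are also in the GR target list, as is Tsc22d3, so the mineralocorticoid list is not separate evidence. In the list of atrophy and autophagy genes 12 of 17 genes rose and 5 were not past, 13 up adjusted over the list alone. Sesn1, a sestrin that restrains mTORC1, rose by 2.91 ± 0.10, Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, by 2.39, and Foxo3, a transcription factor of muscle protein breakdown, by 1.84. The median of that list was 0.85 (camera adjusted p = 1.8e-15; adjusted p = 0.078 with an estimated correlation).

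Among metabolic genes some lists were past the threshold and others were not. In amino acid catabolism 5 of 13 genes rose under CVZ and 8 were not past, 7 up adjusted over the list alone, with a median of 0.38 (camera adjusted p = 7.9e-06; adjusted p = 0.18 with an estimated correlation). They included Glul, glutamine synthetase (log2 1.90), Prodh, proline dehydrogenase (1.57), and Dbt, a subunit of the branched-chain keto acid dehydrogenase (1.03). Pdk4, a kinase that turns off pyruvate dehydrogenase, rose by 2.58, and Pfkfb3, which makes the activator of phosphofructokinase, by 3.04 ± 0.29. Around them the fatty acid list had 2 up, 1 down and 20 not past (camera adjusted p = 0.49), and the glucose list 3 up and 14 not past (0.18). The prostanoid list had 5 up, 1 down and 6 not past (camera adjusted p = 0.015; adjusted p = 0.35 with an estimated correlation), with Ptgs2, Pla2g4a (cytosolic phospholipase A2, 2.04) and Ptgds (prostaglandin D synthase, 1.03) up and the receptor gene Ptgfr down (−1.68). In purine turnover 4 of 12 rose (camera adjusted p = 0.035; adjusted p = 0.27 with an estimated correlation), among them Xdh, xanthine oxidoreductase (log2 1.36), and Gda, guanine deaminase (1.26), whose calls were lost without the first CVZ or the first vehicle array (without the latter 1.00 and 0.95).

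Cytokine and immediate early genes moved both ways under CVZ. Of 20 cytokine and inflammatory genes 8 fell, 3 rose and 9 were not past, with a median of −0.35 (camera adjusted p = 0.021; adjusted p = 0.50 with an estimated correlation). Falls besides Ccl2 and Ccl7 were those of Cxcl1 (a neutrophil chemokine, log2 −1.92), Tnfaip3 (a brake on NF-κB, −1.69), Irf1 (an interferon regulatory factor, −1.49) and Vcam1 (an adhesion molecule, −1.07). Nfkbia, the NF-κB inhibitor, rose by 1.09. In the immediate early list 6 rose, 1 fell and 10 were not past (camera adjusted p = 0.0046; adjusted p = 0.18 with an estimated correlation), with Egr1 up by 2.89 ± 0.10, Fos by 1.98 and Jun by 1.41. The MAPK feedback list had 8 up, 3 down and 8 not past (camera adjusted p = 5.3e-05; adjusted p = 0.11 with an estimated correlation), with Errfi1, an inhibitor of the EGF receptor, at log2 2.10 and Dusp5, an ERK phosphatase, at −1.70. The fetal and hypertrophy list had 3 up, 2 down and 9 not past (camera adjusted p = 0.040; adjusted p = 0.50 with an estimated correlation), where Nppb, which encodes B-type natriuretic peptide, rose by 1.09 and Mef2c, a cardiac transcription factor, fell (−0.78).

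The other lists were not past the threshold under CVZ. The receptor and chaperone list had 1 up and 1 down of 10 (camera adjusted p = 0.66), the clock list 2 up and 3 down of 16 (0.56), ion channels 0 up and 2 down of 18 (0.43), extracellular matrix 4 up of 18 (0.078) and oxidative stress 1 up and 1 down of 16 (0.067). Gja1, which encodes connexin 43, fell by log2 0.54. No gene was called in the proliferation list (0 of 16, 0.87), the cardiomyocyte markers (0 of 15, 0.23) or the epicardial markers (0 of 7, 0.22). Single rises appeared in the fibroblast (1 of 11, 0.83), smooth muscle (1 of 9, 0.49), endothelial (1 of 9, 0.067) and macrophage lists (1 of 11, 0.87). The endothelial rise was that of Kdr, a VEGF receptor (log2 1.83). The erythroid and Schwann lists had 2 measured genes each, too few for a test, and 0 were called. In the receptor, ion channel and macrophage lists the median and the mean had different signs, and in the proliferation list the test ran against both.

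COR raised Fkbp5 14.6-fold (log2 3.87, adjusted p = 1.2e-10, n = 2), to a signal of 27.4 ± 1.1. Klf15 rose by log2 2.62 ± 0.11, Tent5b by 4.40, Spata13 by 3.81, Per1 by 2.99 ± 0.27 (adjusted p = 4.6e-06) and Sesn1 by 2.65. Sult1a1 (3.15), F3 (2.93), Cdc42ep2 (2.34) and Ccl20 (2.87) followed, as did Dgke, a diacylglycerol kinase (2.21), and Rasgrp1, a Ras exchange factor (2.57). Orm1 rose by 3.24 (adjusted p = 2.5e-05) and Ptgs2 by 1.81 (adjusted p = 0.0011). Falls included Sox4 (log2 −1.41 ± 0.11, adjusted p = 1.2e-06), Stc1, a glycoprotein hormone (−1.32 ± 0.14), Sema6d (−1.28) and Rgs2, which ends signalling by G proteins (−0.65 ± 0.11, adjusted p = 0.0017). Ccl2 and Ccl7 were not past the threshold (adjusted p = 0.083 and 0.61).

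In all COR changed 632 probe sets, 454 up and 178 down (276 and 117 genes), of which 267 changed at least 2-fold, and with trimmed-mean scaling 271 were down. The count was 341 without the first COR array and 381 without the second. Among the GR targets 19 of 23 rose and 4 were not past, also 19 adjusted over the list alone, with a median of 1.12 and medians of 1.11 and 1.05 within the experiments (camera adjusted p = 2.5e-32; adjusted p = 0.062 with an estimated correlation). The atrophy and autophagy list had 9 up and 8 not past, 10 up adjusted over the list alone (camera adjusted p = 2.5e-18; adjusted p = 0.062 with an estimated correlation). The mineralocorticoid targets had 5 up and 8 not past, 7 up adjusted over the list alone (camera adjusted p = 4.7e-08; adjusted p = 0.14 with an estimated correlation). Amino acid catabolism had 4 up and 9 not past (camera adjusted p = 3.9e-05; adjusted p = 0.26 with an estimated correlation), with Prodh at 1.36. Immediate early genes had 3 up, 1 down and 13 not past (camera adjusted p = 0.0027; adjusted p = 0.20 with an estimated correlation), with Egr1 at 2.12 and Jun at 1.05. These 5 lists were past the threshold, and 10 were without the second vehicle array. Of 70 named genes 56 lost the call without the experiment term and 34 when 1 array was left out, the latter including Sgk1 and Rgs2 (0.83 and −0.54 without the first COR array).

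ALD raised many of the genes that led under CVZ and COR. Fkbp5 rose 6.47-fold (log2 2.69, adjusted p = 1.4e-08, n = 2) to 12.2 ± 1.8, Tent5b by 3.46 (adjusted p = 1.7e-08), Spata13 by 2.74, Per1 by 2.38 ± 0.27 (adjusted p = 0.00014) and Rasgrp1 by 2.34. Sesn1 (1.99), F3 (1.97, adjusted p = 7.3e-07), Ccl20 (1.96), Sult1a1 (1.95), Klf15 (1.77 ± 0.11, adjusted p = 8.5e-08), Kdr (1.41) and Egr1 (1.02, adjusted p = 3.9e-05) also rose. Orm1 was not past the threshold (log2 1.48, adjusted p = 0.066), nor was Ptgs2 (0.36, adjusted p = 0.80). Falls included Sema6d (log2 −0.84), Sox4 (−0.83 ± 0.11), Stc1 (−0.73) and Rgs2 (−0.80 ± 0.11, adjusted p = 0.00072), with the calls of Stc1 (then −0.59) and Sema6d (−0.84) lost without the first vehicle array. ALD changed 177 probe sets, 162 up and 15 down (92 and 9 genes; 37 down under quantile normalization and 26 with trimmed-mean scaling), 69 of them at least 2-fold, and the count was 117 without the second vehicle array. The GR targets had 8 up and 15 not past, 14 up adjusted over the list alone, with a median of 0.46 (camera adjusted p = 1.3e-18; adjusted p = 0.10 with an estimated correlation). The atrophy and autophagy list had 5 up and 12 not past, 10 up adjusted over the list alone (camera adjusted p = 4.7e-13; adjusted p = 0.10 with an estimated correlation). Mineralocorticoid targets had 2 up and 11 not past, 5 up adjusted over the list alone (camera adjusted p = 0.00044; adjusted p = 0.35 with an estimated correlation), and amino acid catabolism 1 up and 12 not past (camera adjusted p = 0.025; adjusted p = 0.50 with an estimated correlation). Lists past the threshold numbered 4, and 8 without the second vehicle array, 7 without the second ALD array and 7 under quantile normalization. Of 34 named genes 28 lost the call without the experiment term and 15 when 1 array was left out, and Fkbp5, Tent5b, Spata13, F3, Sesn1 and Rasgrp1 were kept in all of these.

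**Figure D2:**
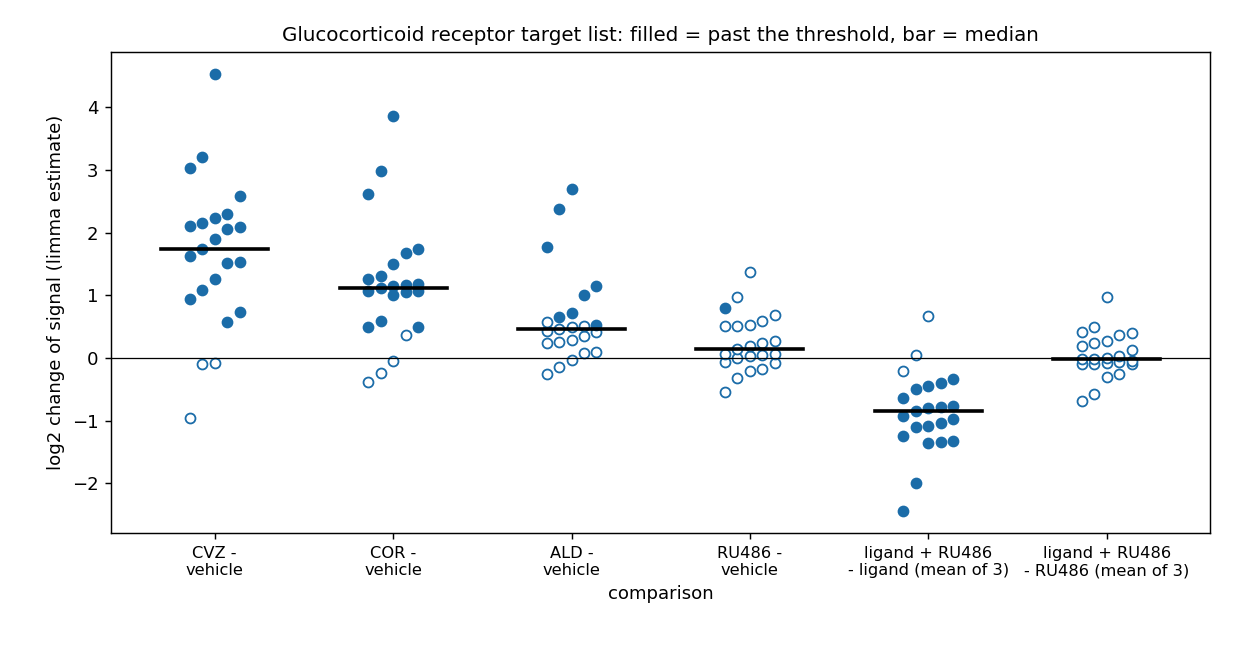
Log2 change of the 23 measured GR targets in 6 comparisons; each point is 1 gene, filled where it was past the threshold, and the bar is the median. The medians were 1.74 for CVZ, 1.12 for COR, 0.46 for ALD and −0.84 for RU486 on top of the ligands.

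COR and ALD changes lay largely within those of CVZ, while most CVZ changes were not called under the other two. CVZ and COR had 429 rises and 141 falls in common and 1 opposite call, against 21.7 and 5.68 expected, and of the COR calls 90.2% were also CVZ calls. ALD shared 157 rises with CVZ (7.73 expected) and 156 with COR (3.95 expected), and 96.6% of ALD calls were COR calls. The correlation across genes was 0.738 for CVZ with COR, 0.605 for CVZ with ALD and 0.688 for COR with ALD. Simulated noise without any response gave 0.499 from the shared vehicle arrays alone, which is not a share of these values. With different vehicle arrays it was 0.361 or 0.370 for CVZ with COR, 0.217 or 0.219 for CVZ with ALD and 0.202 or 0.217 for COR with ALD. These values use single arrays of different experiments, whose noise lowers a correlation but not, on average, a covariance. After removal of the simulated vehicle part the covariance was 0.104 for CVZ with COR, 0.0607 for CVZ with ALD and 0.0510 for COR with ALD. With different vehicle arrays it was 0.0981 or 0.0988, 0.0517 or 0.0545 and 0.0401 or 0.0456. Genes are not independent replicates, and part of the excess may come from shared controls. Averaged over the ligands 1013 probe sets changed, 692 up and 321 down (482 down with trimmed-mean scaling), among them Spata13 (13.2-fold) and Fkbp5 (13.0-fold), and the count was 643 without the first vehicle array and 635 without the second. On this average 19 GR targets, 9 atrophy and autophagy genes and 5 MAPK feedback genes rose, while 2 MAPK feedback genes fell (camera adjusted p = 1.4e-31, 3.0e-17 and 0.018; with an estimated correlation 0.068, 0.068 and 0.22).

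CVZ went beyond COR in chemokines and in several GR targets. Ccl2 was higher under COR than under CVZ by log2 2.09 (95% interval 1.69 to 2.50, adjusted p = 0.00025, n = 2), and Ccl7 by 2.58 (1.92 to 3.24, adjusted p = 0.00094). In the first and second experiment Ccl2 changed by −0.13 and −1.19 under COR and by −2.76 and −2.75 under CVZ. The difference within each experiment lies outside the Ccl2 interval, which leans on the variance shared by all probe sets. Lower under COR were Ptgs2 (−2.15, −2.77 to −1.53, adjusted p = 0.0028) and Slc7a6, an amino acid transporter (−1.45, −1.79 to −1.10, adjusted p = 0.00052). Rgs2 was lower under COR at log2 −1.04 (−1.27 to −0.81, adjusted p = 0.00028). Per1 was not called (−0.05, −0.63 to 0.53), nor was Tent5b (−0.49, −0.88 to −0.11) or Kdr (0.17, −0.23 to 0.57), and a missed threshold does not show that COR and CVZ act alike. In all 180 probe sets differed, 58 higher and 122 lower under COR. Among GR targets 8 were lower and 15 not past, 14 lower adjusted over the list alone (median −0.50, camera adjusted p = 1.4e-18; adjusted p = 0.15 with an estimated correlation). Mineralocorticoid targets had 5 lower (camera adjusted p = 1.7e-07; adjusted p = 0.15 with an estimated correlation), MAPK feedback 4 lower (camera adjusted p = 1.2e-05; adjusted p = 0.15 with an estimated correlation) and cytokines 3 higher and 1 lower, 10 and 3 adjusted over the list alone (camera adjusted p = 0.00017; adjusted p = 0.36 with an estimated correlation). The count was 102 without the first CVZ array, 81 without the second, 58 without the first COR array and 18 without the second. It was 0 without the experiment term, where all 28 named genes lost the call, and 0 without the trend, and the calls of Ccl2, Ccl7, Ptgs2, Rgs2 and Slc7a6 stood under each scaling, pseudocount and left-out array.

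ALD differed from CVZ at 792 probe sets, 304 higher and 488 lower. Orm1 was lower under ALD at log2 −4.00 (95% interval −4.75 to −3.25, adjusted p = 4.4e-06, n = 2), Ptgs2 at −3.61 (−4.22 to −2.99, adjusted p = 1.8e-06), Pfkfb3 at −3.22 (−3.84 to −2.61) and Fkbp5 at −1.84 (−2.13 to −1.55). The Otulin-like gene Otulinl was lower too (−2.51). Ccl2 was higher by 2.39 (1.98 to 2.80, adjusted p = 1.8e-06) and Ccl7 by 2.61 (1.96 to 3.27), and Nr3c1 by 0.54, a call lost without either CVZ array (0.48 and 0.60). Rasgrp1, one of the strongest ALD genes, was not called (−0.29, −0.84 to 0.25), which does not show equal action. GR targets had 18 lower and 5 not past, 20 lower adjusted over the list alone (median −1.05, camera adjusted p = 4.5e-32; adjusted p = 0.068 with an estimated correlation). MAPK feedback had 10 lower and 2 higher (camera adjusted p = 2.0e-06; adjusted p = 0.069 with an estimated correlation), and immediate early genes 5 lower and 1 higher (camera adjusted p = 0.0049; adjusted p = 0.19 with an estimated correlation). The count was 510 without the first CVZ array, 506 without the second and 486 without the first ALD array. It was 21 without the experiment term, where 72 of 79 named genes lost the call, and 78 without the trend.

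Against COR, ALD gave 55 differing probe sets, 6 higher and 49 lower. Egr1 was lower at log2 −1.09 (95% interval −1.31 to −0.87, adjusted p = 0.00039, n = 2), Fkbp5 at −1.17 (−1.46 to −0.88, adjusted p = 0.0017), Klf15 at −0.85 (−1.08 to −0.62) and Pfkfb3 at −1.99 (−2.60 to −1.38, adjusted p = 0.0076). Pdk4 was lower at −1.04, Arrdc2, an arrestin-domain protein, at −1.23 and Ptgs2 at −1.46 (−2.08 to −0.84, adjusted p = 0.047), the last lost under other scalings. Rasgrp1 (−0.23, −0.78 to 0.31) and Rgs2 (−0.15, −0.38 to 0.08) were not called, which does not show that COR and ALD act alike on them. GR targets had 6 lower and 17 not past, 16 lower adjusted over the list alone (median −0.60, camera adjusted p = 1.6e-29; adjusted p = 0.077 with an estimated correlation). The atrophy and autophagy list had 4 lower (camera adjusted p = 2.3e-11; adjusted p = 0.13 with an estimated correlation), and the mineralocorticoid targets 0, or 3 lower adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.23 with an estimated correlation). The count was 2 without the first COR array, 31 without the second, 12 without the first ALD array and 34 without the second, and of the 19 named genes only Egr1 kept its call in each. Without the experiment term and without the trend it was 0, and 5 lists instead of 8 were past the threshold without the first COR array.

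**Figure D3:**
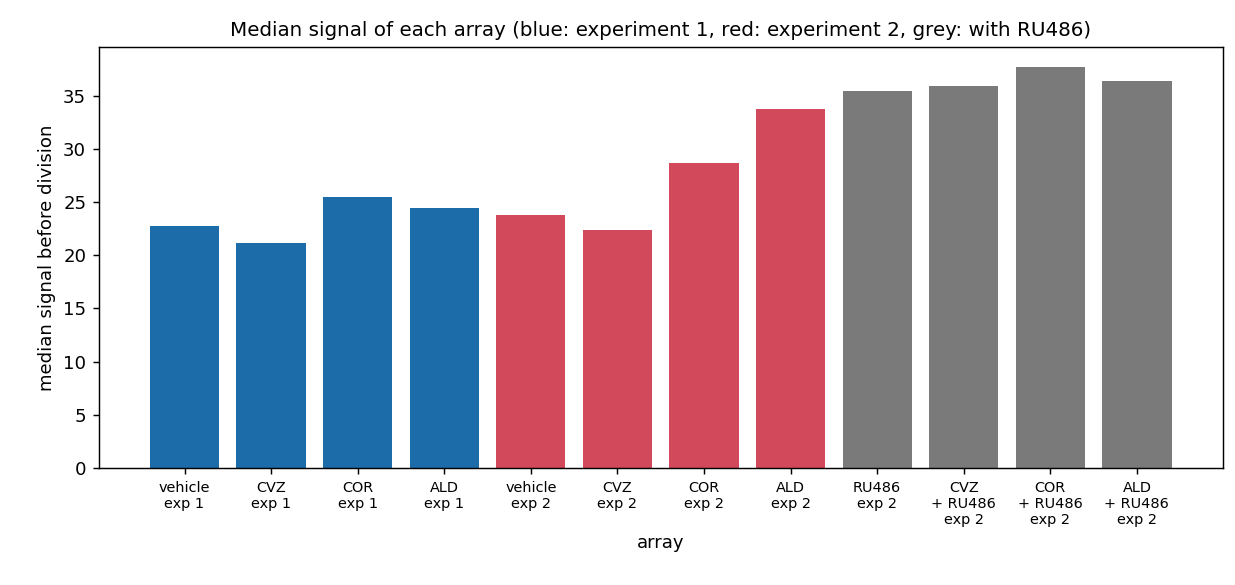
Median signal of each array before division by that median, by condition and experiment; each bar is 1 array. It was 35.4 for RU486 alone, 23.8 for the vehicle of the same experiment and 33.7 for ALD of that experiment.

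RU486 alone raised genes of the integrated stress response and lowered a lipid exporter. Ddit3, which encodes the stress factor CHOP, rose by log2 1.43 ± 0.16 (adjusted p = 0.0014, n = 1 against 2), from 6.18 ± 0.33 to 16.7, and Trib3, a pseudokinase that answers CHOP, by 1.62 ± 0.24 (adjusted p = 0.0091). Hmox1, heme oxygenase 1, rose by 1.01 (adjusted p = 0.0076), Slc3a2, an amino acid transporter chain, by 1.17 (adjusted p = 0.016), and Nppb by 1.00. Abcg1, which exports cholesterol, fell by log2 1.47 ± 0.20 (adjusted p = 0.0051), from 6.31 to 2.67. Klf15 rose by 0.80 (adjusted p = 0.029), Sesn1 by 0.92 and Tent5b by 1.43, in the direction of the ligands. RU486 changed 24 probe sets, 20 up and 4 down, and 14 of the 20 rises were also CVZ rises, an overlap that the vehicle arrays shared by both comparisons may raise. Of the GR targets 1 rose and 22 were not past, 5 up and 1 down adjusted over the list alone (median 0.14, camera adjusted p = 0.044; adjusted p = 0.49 with an estimated correlation). The atrophy and autophagy list had 2 up (camera adjusted p = 6.8e-05; adjusted p = 0.38 with an estimated correlation) and the proliferation list 0 called with a median of −0.15 (camera adjusted p = 0.0030; adjusted p = 0.49 with an estimated correlation). The count was 11 without the second vehicle array, 39 without the first ALD array and 42 without the second, and 0 without the experiment term and without the trend. Leaving out the second vehicle array ended the calls of Trib3 (then 1.45), Hmox1 (1.03), Sesn1 (0.76), Nppb (0.88), Tent5b and Slc3a2, and either COR array that of Klf15, while Ddit3 and Abcg1 kept theirs.

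On top of the ligands RU486 brought many of the steroid-raised genes down. Fkbp5 fell by log2 2.44 ± 0.11 (adjusted p = 7.0e-09, 3 arrays with RU486 against 6 without), and the signals with RU486 were 4.25 for CVZ, 4.85 for COR and 5.33 for ALD beside 2.40 for RU486 alone. Orm1 (−2.70 ± 0.28, adjusted p = 2.3e-05), Spata13 (−2.55), Crispld2 (−2.15), Pfkfb3 (−1.91), Klf9, a Krüppel-like factor (−1.35), and Sesn1 (−0.95) fell as well. Rises were those of Ddit3 (log2 1.45 ± 0.10, adjusted p = 3.9e-07), Hmox1 (1.07, adjusted p = 3.2e-06), Sox4 (1.29), Ccl2 (0.82, adjusted p = 0.0035), Dusp5 (1.15) and Nr3c1 (0.51, adjusted p = 0.0042), so that Sox4, Ccl2, Dusp5 and Nr3c1 moved against their change with CVZ. Without the experiment term the estimates for Ccl2 and Cxcl1 changed sign, to −0.12 and −0.10. RU486 on top changed 907 probe sets, 350 up and 557 down. The split was 483 and 476 under quantile normalization and 460 and 539 with trimmed-mean scaling. Of the 889 CVZ rises 384 were lowered and 2 raised further, of the 454 COR rises 287 were lowered, and of the 162 ALD rises 131, all in the mean over the ligands, which the stronger ligands can carry. The step differed by ligand and gene: it was −0.64 with ALD and −1.97 with CVZ for Klf15, and −1.90 and −1.46 for Per1, with 1 array each. Of the 594 CVZ falls 210 were raised, and of the 178 COR falls 93. These sets were chosen with the ligand arrays that are subtracted here, which favours a move back, and no value for chance was computed. The count was 551 without the second CVZ array, 568 without the second COR array, 49 without the experiment term and 43 without the trend. Of 86 named genes 70 lost the call without that term, 34 when 1 array was left out and 13 under another scaling.

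By group, 20 of 23 GR targets fell with RU486 on top and 3 were not past, 20 also adjusted over the list alone (median −0.84, camera adjusted p = 9.0e-29; adjusted p = 0.080 with an estimated correlation). Mineralocorticoid targets had 9 down (camera adjusted p = 4.4e-10; adjusted p = 0.097 with an estimated correlation) and the atrophy and autophagy list 7 down (camera adjusted p = 2.4e-10; adjusted p = 0.097 with an estimated correlation). Prostanoid genes had 4 down and 1 up (camera adjusted p = 0.0020; adjusted p = 0.22 with an estimated correlation), with Ptgs2 at log2 −1.61 and Pla2g4a at −1.37. Smooth muscle genes had 2 down (camera adjusted p = 0.0020; adjusted p = 0.20 with an estimated correlation), with Tagln, an actin-binding protein, at −0.57. Among cardiomyocyte markers 8 of 15 fell, 10 adjusted over the list alone, by small steps such as that of Myh6, the alpha myosin heavy chain (−0.24), with a median of −0.20 (camera adjusted p = 2.1e-07; adjusted p = 0.22 with an estimated correlation). Of the called falls, those of Myl2 (−0.29) and Pln (−0.20) had another probe set that rose without a call (0.67 and 0.18). Under quantile normalization only 1 of those 15 markers was down, and Myh6 was 0.046. In the same arrays the GAPDH 3′ to 5′ ratio was higher (1.13 to 1.18 with RU486, 1.07 to 1.12 in the others of the second experiment), and the GAPDH 5′ signal lower (180.0 to 205 and 214 to 219). Csrp3, a muscle LIM protein, fell by log2 0.32, and the calls of Myh6 and Csrp3 were lost without the second CVZ array (then −0.25 and −0.28). The glucose list had 3 down and 14 not past (camera adjusted p = 0.00015; adjusted p = 0.22 with an estimated correlation) and was not past under quantile normalization.

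The ligand response itself was smaller with RU486. The interaction of ligand and RU486 was −2.72 for Fkbp5, −3.41 for Tent5b, −3.37 for Per1, −3.30 for Orm1 and −3.18 for Spata13, and 1.17 for Sox4, whose fall was smaller. The Per1 value also holds a higher signal in the lone array with RU486 alone (1.84, vehicle 0.525 ± 0.47). Against that array Per1 with RU486 stood at −0.09 for CVZ, −0.75 for COR and −0.88 for ALD. The interaction was called for 203 probe sets, 23 up and 180 down. Of the 180, 177 were CVZ rises, an overlap that is favoured because both comparisons use the same CVZ and vehicle arrays. The count was 0 without the experiment term and 0 without the trend. GR targets had 13 down and 10 not past, 18 down adjusted over the list alone (median −1.11, camera adjusted p = 5.1e-31; adjusted p = 0.071 with an estimated correlation), and the atrophy and autophagy list 5 down (camera adjusted p = 8.6e-17; adjusted p = 0.071 with an estimated correlation). Against RU486 alone, ligands given after RU486 changed 0 probe sets in limma (n = 3 against 1), with 462 at unadjusted p below 0.05, where 931 would be expected by chance, and a lowest adjusted p of 0.24. The count was 3 without the first or second vehicle array, 1 without the first or second ALD array and 2 under quantile normalization. Fkbp5 still stood at log2 0.98 (adjusted p = 0.24). Kdr stood at 0.82 for CVZ, 1.30 for COR and 1.10 for ALD above RU486 alone, without a call. The 3 arrays are of 3 ligands with 1 array each, and the low number of small p-values means that the test may be too cautious here. That 0 were called therefore does not show that no ligand response was left. GR targets had 0 called, a median of −0.02, a mean of 0.05 and a camera test upward (adjusted p = 0.0076; adjusted p = 0.71 with an estimated correlation). Cardiomyocyte and fetal genes had 0 called (medians −0.13 and −0.16, camera adjusted p = 1.2e-08 and 2.4e-07; adjusted p = 0.71 for both with an estimated correlation), and fry called 0 lists.

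A set chosen in the first experiment was read in the second. Probe sets at least 2-fold up under each ligand in the first experiment numbered 169, from 117 genes. All 3 changes subtract the same vehicle array, so the choice also favours probe sets that read low in it. In the first experiment the medians of the 169 were 2.05 for CVZ, 1.93 for COR and 1.66 for ALD. In the second their median response to the ligands was log2 0.448, with 62 again at least 2-fold. With RU486 it was 0.124 against RU486 alone, or 27.6% of the response, and 5 were at least 2-fold. With RU486 alone the same set stood at 0.186 above vehicle, and the ligands with RU486 stood at 0.279. By ligand the medians without and with RU486 were 0.688 and 0.130 for CVZ, 0.438 and 0.0960 for COR, and 0.461 and 0.170 for ALD. The response without RU486 was 0.96 with 4 times the pseudocount, 0.043 without the expression filter, where it was 0.096 with RU486 and so not smaller, and 0.67 when the set was chosen in the second experiment and read in the first, where no RU486 array exists. With RU486 it was 0.18 with 4 times the pseudocount and 0.073 when a 1.5-fold choice was made. In the 429 probe sets raised by both CVZ and COR, a set chosen after the data had been seen and partly with the arrays it is read in, the medians were 0.986 without and 0.0929 with RU486, or 9.42% of the response. There RU486 alone stood 0.305 above vehicle and the ligands with RU486 0.396, or 40.1% of the response.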

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

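The test of a single unusual array and the ATF4-linked list were chosen only after results had been seen, and the tests on cardiomyocyte markers were set after the fall of the markers but before their own values were known. The other tests were written beforehand.

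The ligand response differed between arrays with and without RU486 at 203 probe sets, most often as a smaller response with RU486. The interaction was −3.41 for Tent5b, −3.37 for Per1, −3.30 for Orm1, −3.18 for Spata13 and −2.72 for Fkbp5. For Per1 it also holds a higher signal in the lone array with RU486 alone (1.84, vehicle 0.525 ± 0.47). The interaction was positive for Ring1 (2.45), Tmem51 (1.32), Sema6d (1.22), Sox4 (1.17) and Ptgfr (1.02). Tmem51, Sema6d, Sox4 and Ptgfr were lower with the ligands, so that their response was smaller with RU486 too, while the value of Ring1, a polycomb protein, comes from a low signal in the lone array with RU486 alone (0.153, beside 0.916, 0.798 and 1.11 with ligands) and from 1 of its probe sets only (the other 0.55 with RU486 alone). The 4 arrays with RU486 were bright before division by the median (RU486 alone 35.4, with CVZ 35.9, with COR 37.7, with ALD 36.4), but so was the ALD array of the second experiment (33.7). If brightness could shrink a response, ALD should have responded less in the second experiment than in the first. Its median response was 1.36 times as large, but this cannot decide the question. In the bright ALD array the median change from its dim vehicle was −0.057 in decile 1 of mean signal and 0.127 in decile 10. The responses with RU486, in contrast, set bright arrays against a bright one. The value also rests on 1 array, less bright than those with RU486, so brightness stays open. Only 10 splits of the 6 ligand arrays exist, too few for a share under 0.05; the real split called 247 probe sets, the highest other 0, and 1 split reached the real value.

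ATF4-linked genes were higher with RU486 alone, a contrast that rests on 1 RU486 array. A single unusual array could explain this only if the 3 other RU486 arrays did not show it, and there the median of the list was 0.45 above the same ligand alone, with 24 of 25 genes up. Array brightness should have raised the list in the bright ALD array, and the ALD change in the second experiment minus that in the first was −0.077, which argues against brightness but again rests on 1 bright array and excludes nothing. Signs of handling moved with RU486 as well: within the second experiment the GAPDH 3′ to 5′ ratio was 1.13 to 1.18 with RU486 and 1.07 to 1.12 without, and the 5S rRNA control 5.05 to 6.26 and 3.83 to 5.12, whereas the actin ratio was 1.92 to 2.11 and 1.96 to 2.26. Whether RNA quality contributes was not tested.

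Cardiomyocyte markers were lower with RU486 on top of the ligands, with a median of −0.21 in the second experiment. Brightness should have lowered them in the ALD array of that experiment too. Their ALD change was 0.13 higher than in the first experiment, in that 1 array. However, all probe sets in decile 10 of mean signal had a median of 0.127 above vehicle there, and the markers 0.041. The value therefore cannot decide, and brightness stays open. Compression of abundant probe sets may contribute: 884 other probe sets in the same range of signal had a median of −0.11, and the difference from the markers, 0.10, cannot tell the explanations apart. Under quantile normalization 1 marker was down instead of 8, and with a trimmed mean 8 were.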

How the results depend on the processing

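Trimmed-mean scaling, single-symbol probe sets and the set of genes raised by both CVZ and COR were tests chosen only after results had been seen. Without the experiment block the counts were 202 for CVZ, 42 for COR, 13 for ALD, 100 for the mean of the ligands, 0 for COR against CVZ, 21 for ALD against CVZ, 0 for ALD against COR, 0 for RU486 alone, 49 for RU486 on top and 0 for the interaction, and lists past the threshold were 7 for ALD against CVZ and 5 for ALD against COR. This follows from construction, since differences between experiments then enter the error; Ccl2 (−0.12) and Cxcl1 (−0.10) with RU486 on top changed sign because the ligand arrays of the first experiment then enter unadjusted. Without a trend the counts in the same order were 646, 117, 15, 264, 0, 78, 0, 0, 43 and 0, and the cause was not tested. A 2-fold minimum left 630 for CVZ, 267 for COR, 69 for ALD, 279 for their mean, 51 for COR against CVZ, 288 for ALD against CVZ, 20 for ALD against COR, 139 for RU486 on top and 125 for the interaction, fewer by construction. A 2-fold change in both experiments without a test gave 474 for CVZ, 201 for COR, 77 for ALD, 195 for their mean, 74 for COR against CVZ and 248 for ALD against CVZ. With 1 probe set per gene CVZ had 932 and ALD 114, from fewer tests. Without the filter COR against CVZ had 106, ALD against COR 21 and RU486 alone 13, and the median response of the genes chosen in the first experiment was 0.043, below its value of 0.096 with RU486; the cause was not tested. Quantile normalization gave 2 for ligand plus RU486 against RU486 and 7 lists for ALD, and with RU486 on top turned Ldhb to 0.033 and Myh6 to 0.046; the cause was not tested. It gave 51.9% rises for CVZ and 50.4% for RU486 on top instead of 59.9% and 38.6%, and trimmed-mean scaling 49.2% and 46.0%. The falls were 266 and 271 for COR and 37 and 26 for ALD under quantile normalization and trimmed-mean scaling. For the chosen genes the median response was 0.96 with 4 times the pseudocount, 0.67 when chosen in the second experiment and read in the first, and 0.99 for genes raised by both CVZ and COR; with RU486 it was 0.18 with 4 times the pseudocount and 0.073 after a 1.5-fold choice. The cause was not tested. Leaving out 1 array gave 341 to 692 for COR, 117 to 186 for ALD, 635 to 1019 for their mean with CVZ, 18 to 238 for COR against CVZ, 486 to 851 for ALD against CVZ, 2 to 71 for ALD against COR, 11 to 42 for RU486 alone, 551 to 1042 for RU486 on top and 0 to 3 for ligand plus RU486 against RU486. Lists were 5 to 10 for COR, 3 to 8 for ALD and 5 to 10 for ALD against COR. The cause was not tested. Leaving out a lone RU486 array left the comparisons that need it without a value. With an estimated correlation 0 of the 24 lists fixed beforehand were past the threshold in each of the 11 comparisons. That form of camera rests on the 3 residual degrees of freedom. A high correlation is not needed for such a loss. The sterol list under CVZ had an estimated correlation of −0.06, below the preset 0.01, and its unadjusted camera p went from 2.4e-08 to 0.0093. With fry the lists were 2 for COR against CVZ, 4 for ALD against COR, 1 for RU486 alone, 5 for the interaction and 0 for ligand plus RU486 against RU486, and the cause was not tested.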

Other observations

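The sterol, ATF4-linked and endoplasmic reticulum lists were tests chosen only after results had been seen, whereas the tests of the ALD response were written beforehand, with the brightness value already seen as a descriptive number when its test was put back after a slip. CVZ lowered genes of sterol synthesis, a pathway switched on by SREBP2 when membrane cholesterol is low. Of 16 measured genes 6 fell and 10 were not past the threshold, 10 down adjusted over the list alone (median log2 −0.41, camera adjusted p = 7.3e-08; adjusted p = 0.028 with an estimated correlation). They were Msmo1, the sterol C4 methyl oxidase (−0.80), Mvd, mevalonate decarboxylase (−0.76), Cyp51, lanosterol demethylase (−0.50), Dhcr7 (−0.49), Fdft1, squalene synthase (−0.46), and Idi1 (−0.39). Under COR and ALD 0 of them were called, and ALD stood above CVZ at 8 (median 0.43; adjusted p = 0.012 with an estimated correlation). Against RU486 alone the ligands with RU486 stood lower (0 called, median −0.26; adjusted p = 0.013 with an estimated correlation), and RU486 alone stood higher than vehicle (0 called, median 0.27; adjusted p = 0.036 with an estimated correlation), both from the same lone array with RU486 alone, so that 1 high array would give both. In the other RU486 arrays, on top of the ligands, the list was not past the threshold (0 called, median −0.03, mean 0.04; adjusted p = 0.63 with an estimated correlation). Dose, and an action of CVZ apart from the GR, were not tested.

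RU486 raised ATF4-linked genes with and without ligand. With RU486 alone 4 of 25 were past the threshold, 17 up adjusted over the list alone (median 0.58; adjusted p = 0.0053 with an estimated correlation), and on top of the ligands 14 were (median 0.43; adjusted p = 0.0076 with an estimated correlation). Besides Ddit3 and Trib3 these included Sesn2 (0.84), a sestrin induced by stress, Atf4 itself (0.63), Asns, asparagine synthetase (0.52), and Psat1, of serine synthesis (0.45), and the interaction called 0. Of 18 genes of the endoplasmic reticulum 2 rose with RU486 alone and 16 were not past the threshold (median 0.20; adjusted p = 0.036 with an estimated correlation), namely Dnajb9 (1.03) and Herpud1 (0.84). On top of the ligands Dnajb9 rose (0.59), Herpud1 (−0.61) and Edem1 (−0.79) fell, and the list was not past the threshold (camera adjusted p = 0.51; adjusted p = 0.64 with an estimated correlation). Since Herpud1 is also raised by CVZ (2.13), its fall there may be the loss of a steroid rise, and the rise of the ATF4-linked list, 0.45 in the arrays with both, may be an effect of 10 µM RU486 apart from the GR. A GR antagonist of another structure, or cells without GR, would test this.

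The smaller response to ALD could be the same program at lower strength. The ALD change was taken as a fixed 0.451 of the CVZ change. This ratio came from the median changes of the 429 probe sets raised by both CVZ and COR in these same arrays. From it 18 probe sets departed, against 792 that differed plainly, a share of 0.023. For COR, at a ratio of 0.812 found alike, 26 departed against 180. A ratio fitted to the same arrays favours fewer departures than a plain difference, so the small share cannot show 1 program at different strengths. For ALD 1416 probe sets departed at unadjusted p below 0.05, where 931 would be expected by chance. Rgs2 departed under both COR and ALD (−0.97 for each), with a small rise under CVZ (log2 0.40, a call lost when 1 array was left out) and falls under COR and ALD, and Ccl2 (1.57) and Ccl7 (2.01) departed under COR. Tent5b and Sesn1 (0.67) rose more under ALD than the ratio gives, and Pfkfb3 (−1.55) and Ptgs2 (−1.43), which were not called under ALD, lay below it. Array brightness would need ALD to be low only in its bright second array, and in the first experiment the COR response was already 1.93 times that of ALD. Those genes were chosen by CVZ and COR calls, which favours such a ratio, but the GR targets, not chosen by calls, had medians of 1.11 for COR and 0.457 for ALD in that experiment. This argues against brightness as the cause, with the limit that the first experiment has 1 ALD array, which alone excludes nothing.

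Aldosterone has an aldehyde at carbon 18 where corticosterone has a methyl, and cortivazol has a phenylpyrazole fused to the A ring. Whether structure or dose makes the difference in Ccl2 and Rgs2 was not tested.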
